A study of Mus musculus with 6 samples.

How the data were processed

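RNA was measured in 6 libraries, 3 from control and 3 from SLE1.2.3 mice, each from naive CD4 T cells cultured for 5 days with 10 µg/mL of antibodies to IL-4 and interferon-γ, 1 ng/mL TGF-β1, 10 ng/mL IL-23, 50 ng/mL IL-6 and 10 ng/mL IL-1β. Libraries were made from polyadenylated RNA with a SMARTER kit, per the labels' protocols. The submitters' processing notes name FastQC 0.11.9, cutadapt 2.10, STAR 2.7.3a, featureCounts 2.0.0, DESeq2 1.24.0 and the genome build mm10, with no role or order. The strand setting of the counting and the annotation release are not given in the sources used here. Without a stated strand, reads of overlapping antisense genes cannot be told apart.

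The authors deposited a table of FPKM values for 33300 features with their coordinates, lengths and biotypes. In each column the value times the length in kb sums to 1000000, so the values are relative to the reads assigned to these features. 32630 of the feature IDs matched GENCODE M21 with their version and had the same coordinates there, and 33204 matched without the version. 24 symbols had been turned into dates by a spreadsheet and were restored from the ID; 14 of these were tested. No 2 libraries held identical values.

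Depth was recovered from the values. The authors' FPKM steps at low values are whole multiples of 1 read, and the smallest step at which the low values came out whole, within 0.15 of a read, gave the number of assigned reads per library. 100.0% of the low values checked, those under 30 reads, were whole in every library. A gene listed at 0 could be present at up to 3 reads, which is between 0.0359 and 0.101 per 1000000 assigned reads. Precision for low genes is therefore lowest in control 3, and such limits cover counting error only.

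Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 11378 in all. Values were transformed to log2(FPKM + 1), a scale that understates the change of low genes, and fitted with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend) with genotype as the only term. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05, and each adjusted p for a gene comes from this fit. The p-values measure the spread between these mice. The file holds no counts, so the count test foreseen for count files was not used as the main test.

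Before the data were examined, 39 gene lists with 706 entries were fixed, for T cell states, cytokine responses, metabolism, cycling, interval candidates, other cell types and library quality; 705 entries matched a feature. The 36 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, then with an estimated correlation, and with fry. Of these 36, 19 passed with the preset correlation, 11 higher and 8 lower, and 0 passed with an estimated one; fry called 18 for direction and 30 for change in either direction. Shares of called genes were compared by chromosome and in bins of 10 Mb with at least 10 tested genes by two-sided Fisher's exact test, adjusted over chromosomes or bins.

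Genes were named by a rule set before the data were examined. It takes the 15 largest changes in each direction among genes past the threshold whose groups do not overlap, with predicted genes, pseudogenes, RIKEN and Gm symbols counted but not named. It also takes up to 4 members of each list with the smallest adjusted p, or up to 2 where none passed, and a fixed set of Th17, cytokine and interval genes. Trdc, Cd4, Cd8a, Cd8b1, Trac, Rpl35a, the copies of Ftl1, Ndufs5, Usf2 and Rpl35a, and the γδ variable genes were chosen after their values were seen. Some genes that the rule takes are not reported here.

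The scripts were tested on simulated data, with counts drawn from the real means and library sizes at a dispersion of 0.02 for the SLE1.2.3 against control comparison. Among 11356 simulated genes, of 100 changed 2-fold 94 were recovered with the right sign, and of 100 changed 4-fold 99 were. Unchanged genes made up 4.35% of the calls. With no gene changed, 0 of 11380 genes passed. With a 30-gene list shifted 1.5-fold, camera gave it an adjusted p of 2.0e-26. The simulation used the same dispersion in both groups and independent genes. The real SLE1.2.3 libraries varied far more than the controls, and members of some lists were correlated. These rates therefore check the scripts and do not give the performance on these data.

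Alternatives were another pseudocount (0.1), no filter or a mean of at least 5 FPKM, rescaling to a common FPKM sum, by median ratio or by quantiles, other variance settings, array weights, the mouse number as a block, each mouse left out, and genes of chromosomes 1, 4 and 7 left out. Chosen after seeing the data were limma voom on the recovered reads, the Trdc level as a covariate, SLE1.2.3 mice 2 and 3 left out together, and ribosomal, small and mitochondrial RNA left out of the scaling. Pseudogenes were matched to protein-coding transcripts with blastn 2.17.0 at 90% identity or more over at least 100 bases. Scripts also ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.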

Results

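The series measured polyadenylated RNA in CD4 T cells that had been driven towards the Th17 state, the helper T cell type defined by interleukin-17 production. Naive CD4 T cells of female mice were stimulated through CD3 and CD28 for 5 days in a medium that held TGF-β1, IL-6, IL-1β and IL-23 together with antibodies that block IL-4 and interferon-γ. The cells of 3 control mice, labelled wild type, were compared with those of 3 SLE1.2.3 mice. SLE1.2.3 is the usual name of a lupus-prone line that carries the susceptibility intervals Sle1, Sle2 and Sle3, which lie on chromosomes 1, 4 and 7. The labels number the mice from 1 to 3 in each group, and each library is named here by its group and mouse number.

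The libraries differed in depth. The reads assigned to genes, recovered from the steps of the FPKM values and given in units of 1000000 reads, came to 50.3, 56.8 and 29.7 for control mice 1, 2 and 3. They came to 83.5, 61.7 and 75.1 for SLE1.2.3 mice 1, 2 and 3, so that the mean depth was 1.61 times that of the controls. Features annotated as ribosomal RNA, or as copies of it, took 2.86% of the assigned reads in control 3 and between 0.202% and 0.304% in the other libraries. Xist, the transcript that silences the X chromosome in female cells, had a level of 45.7 ± 4.34 FPKM in control cells and 42.7 ± 6.21 FPKM in SLE1.2.3 cells (SD, n = 3 each). The first principal component held 78.4% of the variance. Its scores were -28.6, -29.5 and -29.0 for the control libraries and 4.25, 33.9 and 49.0 for SLE1.2.3 libraries 1, 2 and 3, so the SLE1.2.3 libraries were spread far more widely than the controls.

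The design asks which transcripts differ between Th17-differentiated cells of lupus-prone and healthy mice. SLE1.2.3 cells held more RNA of the cytokine genes Il22, Ifng and Il17a, the granzyme gene Gzmb, the receptor genes Cxcr6 and Il23r and the γδ receptor gene Trgc1, and less of Socs2 and Igfbp4. Of 11378 genes tested with limma, 1733 passed an adjusted p of 0.05, with 1098 higher and 635 lower in SLE1.2.3 cells. Rescaling to a common FPKM sum gave 1006 higher and 349 lower, and quantile normalization 969 and 893. In all 1733 the 3 SLE1.2.3 values lay on one side of the 3 control values. With 3 libraries per group, passing the threshold all but requires this. Such a separation was seen in 41.5% of the tested genes, where chance gives 10% on average. Genes move together, so the share in a single grouping can lie far from that average. A change of at least 1 on the log2 scale was reached by 483 of the 1733, of which 341 were higher. The count was 206 without SLE1.2.3 mouse 2, 3705 without SLE1.2.3 mouse 1, and 313, 258 and 272 without control mouse 1, 2 and 3. With SLE1.2.3 mice 2 and 3 both left out, 659 genes passed and 545 of them were among the 1733. That fit has 1 SLE1.2.3 library, takes the spread from the controls and assumes that the lone library varies like them. With the level of the γδ chain Trdc as a covariate, 182 genes passed and 75 of them were among the 1733. The covariate removes part of any change that moves with it. Trdc was far higher in the SLE1.2.3 libraries than in the controls, so the covariate nearly follows genotype. Its slope rests mainly on the 3 SLE1.2.3 libraries, and the genotype term is extrapolated to a shared Trdc level. Calls lost or reversed under it, here and below, therefore do not separate genotype from Trdc.

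Of the 15 largest increases, 4 were predicted genes, pseudogenes or RIKEN clones and the other 11 were named genes. Il22, a cytokine of Th17 and innate lymphocytes, had a level of 424 ± 306 FPKM in SLE1.2.3 cells against 3.72 ± 1.71 FPKM in control cells (SD, n = 3 each), a log2 change of 6.10 ± 0.79 (SE; adjusted p = 0.0095). Ifng, which encodes interferon-γ, had a log2 change of 5.79 ± 0.99 (adjusted p = 0.019), from 1.2 ± 0.32 to 211 ± 201 FPKM. The chemokine receptor Cxcr6 rose from 3.99 ± 1.02 to 250.4 ± 166 FPKM. The granule proteases and pore former of cytotoxic lymphocytes rose as well, with Gzmb at 987 ± 747 against 25 ± 7.1 FPKM and Prf1 at 48.0 ± 39.2 against 0.459 ± 0.0861 FPKM. The γδ receptor genes Trgc1, Trgc2 and Trdv4 had log2 changes of 5.32, 4.42 and 5.04, and Cd163l1, a scavenger receptor family gene, had 4.44. The immunoglobulin constant genes Igkc and Ighg2c had log2 changes of 5.47 and 4.82. SLE1.2.3 library 1 lay well below libraries 2 and 3 for several of these genes, with Gzmb at 177, 1138 and 1648 FPKM. The Trgc genes and the granzyme genes have near-identical relatives, so reads may be split between them. Genes near 0 in the controls, such as Prf1, passed the filter on the mean only through the SLE1.2.3 libraries, so their direction was largely set by it.

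The 15 largest decreases included 1 predicted gene. Htatip2 and Bcam, both on chromosome 7, were at most 0.27 and 0.288 FPKM in the SLE1.2.3 libraries. Htatip2 (chromosome 7, 49759115 to 49773975, mm10) fell from 13.6 ± 0.913 to 0.143 ± 0.115 FPKM (adjusted p = 4.6e-05), and Bcam, an adhesion molecule gene (chromosome 7, 19756131 to 19771016), from 8.75 ± 0.308 to 0.128 ± 0.141 FPKM (adjusted p = 0.00010). Lrrc32, which encodes the TGF-β docking receptor GARP, fell by 2.71 on the log2 scale (SE 0.63; adjusted p = 0.037). Socs2, an inhibitor of cytokine signalling, fell by 2.43, the transglutaminase gene Tgm2 by 2.7, Ccn3 by 2.69, the mucin gene Muc13 by 2.57 and the type I receptor gene Acvrl1 by 2.44. Il24, Cpm, Selenbp1, Fam71b, Igfbp4 and the kinase gene Plk2 fell by 2.42, 2.39, 2.35, 2.34, 2.34 and 2.29. Lrrc32, Tgm2, Muc13, Il24, Selenbp1 and Igfbp4 had a change of the other sign, without passing, once the Trdc level was a covariate.

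**Figure D1:**
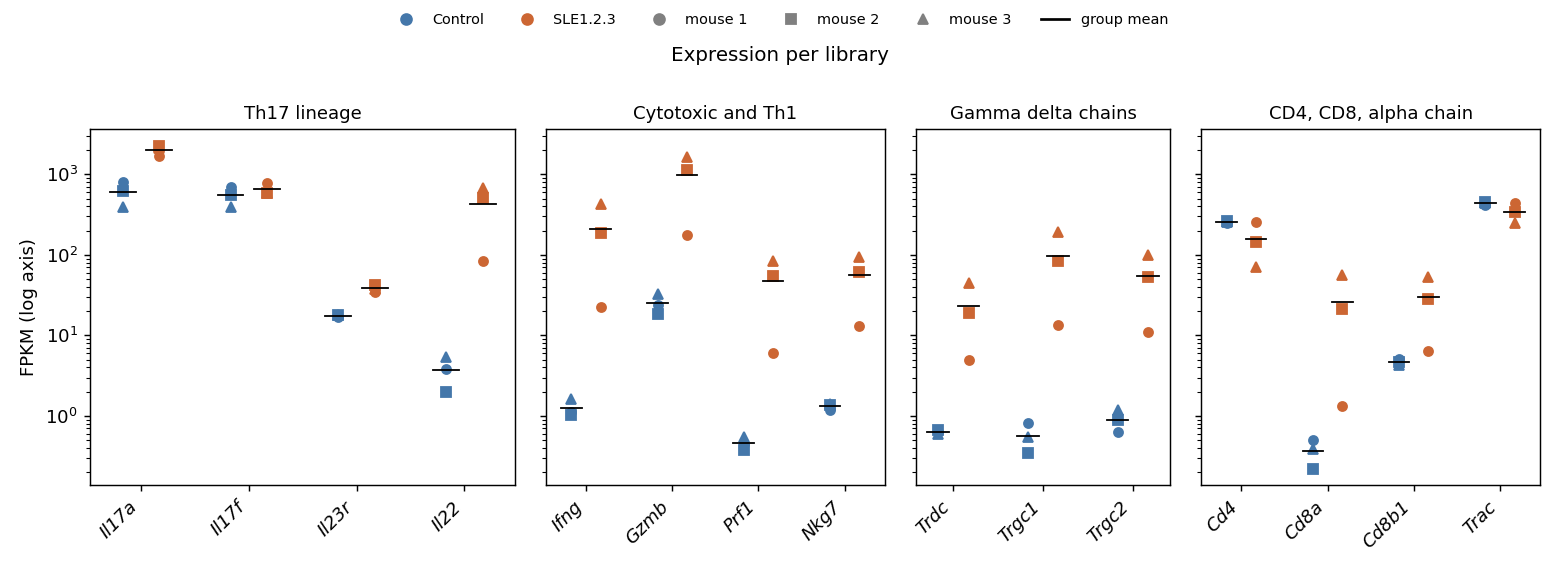
FPKM on a log axis for named genes in each library, with control mice in blue, SLE1.2.3 mice in orange, a marker shape for each mouse and a black line at each group mean. Il23r has a narrow range in both groups, whereas Trdc runs from 4.96 to 45.2 FPKM and Cd8a from 1.34 to 56.4 FPKM over the SLE1.2.3 mice.

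Genes of the Th17 lineage were part of the difference. Of 21 tested members of the Th17 list, 9 rose, 0 fell and 12 did not pass, while 10 rose and 4 fell when adjusted over the list alone. Il17a, the defining cytokine, rose from 604 ± 204 to 2029 ± 313 FPKM (SD, n = 3 each; log2 change 1.79 ± 0.27 SE; adjusted p = 0.014). The transcription factor gene Rora rose by 1.23 on the log2 scale, and the receptor gene Il23r by 1.09. Il10, an anti-inflammatory cytokine gene, rose from 0.868 ± 0.294 to 5.20 ± 1.27 FPKM. Il17f had 550.0 ± 153 and 654 ± 108 FPKM in control and SLE1.2.3 cells (adjusted p = 0.43), and Il21 116 ± 14.8 and 43.7 ± 32.8 FPKM (adjusted p = 0.071), and neither passed. Members of the Th17 list ranked above other genes in limma's camera test (adjusted p = 0.027; adjusted p = 0.39 with an estimated correlation). That call ended without SLE1.2.3 mouse 1 (adjusted p = 0.25) and with the mouse number as a block (adjusted p = 0.056). Trdc, a γδ receptor chain, was at 4.96, 18.9 and 45.2 FPKM in SLE1.2.3 libraries 1, 2 and 3, where Il23r was at 34.8, 42.4 and 37.8 FPKM.

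The list of genes linked to pathogenic Th17 cells, which cause tissue inflammation, had 12 members that rose, 1 that fell and 5 that did not pass among 18 tested. Adjusted over the list alone, 13 rose and 1 fell. Csf2, which encodes GM-CSF, rose from 4.09 ± 0.323 to 24.4 ± 6.89 FPKM, Lgals3 by 1.94 on the log2 scale and Gpr65 by 1.14. The Th1 list had 9 of 12 members that rose and 0 that fell, and the same counts when adjusted over the list alone. Tbx21, the Th1 master regulator, rose from 0.254 ± 0.146 to 9.83 ± 7.16 FPKM, and Cxcr3, Hlx and Ccl5 had log2 changes of 1.44, 2.19 and 2.51. Tbx21 passed the filter on the mean only through the SLE1.2.3 libraries, so its direction was largely set by it. Of the 15 listed Th1 genes 12 were tested. The camera test called the pathogenic Th17 and Th1 lists higher, each with an adjusted p of 1.4e-05 (adjusted p = 0.39 and adjusted p = 0.50 with an estimated correlation). Both lists hold Ifng, Tbx21, Ccl5, Stat4 and Il18r1, and Gzmb is in the pathogenic and cytotoxic lists, so these calls are not independent. Trdc levels of 4.96, 18.9 and 45.2 FPKM in SLE1.2.3 libraries 1, 2 and 3 went with Tbx21 levels of 2.90, 9.41 and 17.2 FPKM. The non-pathogenic list had Il10 as its single called member of 6, or 2 when adjusted over the list alone, and did not pass (camera adjusted p = 0.13), except with SLE1.2.3 mice 2 and 3 left out (adjusted p = 0.0095, from 1 SLE1.2.3 library with the spread of the controls).

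Of 23 tested type I interferon genes, 14 rose and 0 fell, or 17 and 0 when adjusted over the list alone, with Irf9, Stat2 and Isg15 at log2 changes of 0.80, 0.77 and 1.62. Of 21 tested interferon-γ response genes, 16 rose and 0 fell, or 18 and 0 when adjusted over the list alone. Irf1 rose from 11.2 ± 1.76 to 55.0 ± 22.7 FPKM and Irgm1 from 7.35 ± 0.914 to 35.4 ± 15.2 FPKM (SD, n = 3 each). Psmb8, an immunoproteasome subunit gene, rose by 0.45 on the log2 scale, and the GTPase gene Tgtp2 by 3.17. Tgtp2 has a near-identical copy, so its reads may be split between both. The camera adjusted p was 5.0e-06 for the type I list and 3.4e-07 for the interferon-γ list (adjusted p = 0.50 with an estimated correlation for each). With the Trdc level as a covariate the interferon-γ list no longer passed (adjusted p = 0.97); Irf1 was at 29.1, 64.7 and 71.3 FPKM in SLE1.2.3 libraries 1, 2 and 3, where Trdc was at 4.96, 18.9 and 45.2 FPKM.

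Some markers of other lymphocytes were higher in the SLE1.2.3 group. Of 10 tested γδ and NKT cell genes, 8 rose and 0 fell, or 9 and 0 when adjusted over the list alone (camera adjusted p = 0.00012; adjusted p = 0.50 with an estimated correlation). Zbtb16, the transcription factor gene of innate-like T cells, rose from 0.0647 ± 0.0180 to 4.51 ± 1.97 FPKM. The cytotoxic list had 6 of 10 members that rose and 0 that fell, or 8 and 1 when adjusted over the list alone, with Nkg7 at a log2 change of 4.24, Gzma at 3.90 and Gzmc at 4.15 (camera adjusted p = 0.0079; adjusted p = 0.50 with an estimated correlation). The CD8 T and NK cell list had 3 of 6 members that rose and 0 that fell, or 6 and 0 when adjusted over the list alone, with Klrd1 and Klrk1 at log2 changes of 1.96 and 2.77 (camera adjusted p = 0.0012; adjusted p = 0.50 with an estimated correlation). Cd8a was at 1.34, 21.4 and 56.4 FPKM in SLE1.2.3 libraries 1, 2 and 3 and at most 0.508 FPKM in the controls, and did not pass (adjusted p = 0.081). Members near 0 in the controls, such as Cd8a and Zbtb16, passed the filter on the mean only through the SLE1.2.3 libraries. Their direction was thus largely set by the filter. Tested were 6 of 11 listed CD8 T and NK genes, 10 of 13 cytotoxic genes and 10 of 10 γδ and NKT genes. Cd4 was at 257, 144 and 71.6 FPKM in those libraries and at 246, 264 and 253 FPKM in the controls (adjusted p = 0.20). With the Trdc level as a covariate the γδ, cytotoxic and CD8 lists no longer passed (adjusted p = 0.097, 0.60 and 0.35), and since Trdc is itself a member of the γδ list, its loss was largely set by the choice of covariate.

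The B cell list had 4 of 8 members that rose and 0 that fell, with the same counts over the list alone, and did not pass the camera test (adjusted p = 0.16), except with SLE1.2.3 mice 2 and 3 left out (adjusted p = 0.015, from 1 SLE1.2.3 library with the spread of the controls) or the Trdc covariate (adjusted p = 0.0028). Igkc and Jchain rose, as did Cd79b and Blk, and Blk is also a kinase gene of γδ T cells. Of 59 tested immunoglobulin segments 39 passed, all 39 of them higher. A segment near 0 in the controls, such as Ighg2c at 0.0477 FPKM, passed the filter on the mean only through the SLE1.2.3 libraries. The direction of such segments was thus largely set by the filter. The myeloid list had Ifitm3 higher and Cd68 lower among 6 tested, with the same counts when adjusted over the list alone (camera adjusted p = 0.82). Its median and camera direction were negative, and its mean and fry direction positive. The median turned positive, at 0.078, when rescaled to a common FPKM sum, and the camera direction turned positive under quantile normalization. Among the dendritic and red cell lists, which had too few tested members for a list test, Xcr1 and Pf4 rose by 1.88 and 1.81 on the log2 scale.

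Chemokine receptor and homing genes had 11 of 20 tested members that rose and 0 that fell, or 13 and 2 when adjusted over the list alone (camera adjusted p = 0.00069; adjusted p = 0.39 with an estimated correlation). Ccr1 rose from 2.25 ± 0.202 to 35.2 ± 11.4 FPKM and Ccr2 from 10.3 ± 2.65 to 95.3 ± 45.4 FPKM. The TGF-β response list had 4 of 14 members that rose, namely Tgif1, Ltbp3, Tgfbr2 and Ldlrad4, or 6 when adjusted over the list alone (camera adjusted p = 0.029; adjusted p = 0.39 with an estimated correlation). That call ended when the values were rescaled to a common FPKM sum (adjusted p = 0.056), without control mouse 2 (0.061), without SLE1.2.3 mouse 1 (0.059) and with the Trdc covariate (0.49). Inhibitory receptor genes had 4 of 10 that rose, with Tigit, Pdcd1, Havcr2 and Entpd1 at log2 changes of 2.24, 2.09, 2.77 and 0.77, or 5 that rose and 3 that fell when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.26; 0.047 with the Trdc covariate).

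Of the 8 lists that camera called lower, 1, the SLAM family, also passed fry's directional test, which does not compare a list with other genes. For the other 7 the fry adjusted p lay between 0.087 and 0.48. The naive and memory list had 2 members lower, among them Igfbp4, and 12 of 14 members that did not pass, or 4 lower when adjusted over the list alone (camera adjusted p = 0.0024; adjusted p = 0.55 with an estimated correlation). That call ended with SLE1.2.3 mice 2 and 3 left out (adjusted p = 0.43, from 1 SLE1.2.3 library with the spread of the controls), and with the Trdc covariate the direction was reversed (adjusted p = 4.8e-05). The hypoxia list had Egln3 lower, by 2.07, and 13 members that did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.00029; adjusted p = 0.50 with an estimated correlation). Of 34 tested cell cycle genes 7 fell and 0 rose, or 13 and 0 when adjusted over the list alone, with Bub1b, Aurkb, Mcm7 and Gins2 at log2 changes of -0.56, -0.50, -0.46 and -0.38 (camera adjusted p = 5.4e-07; adjusted p = 0.50 with an estimated correlation). The glycolysis list was lower in the camera test (adjusted p = 7.2e-05; adjusted p = 0.50 with an estimated correlation) although 0 of its 22 members passed, over all genes or adjusted over the list alone, and the call ended with the Trdc covariate (adjusted p = 0.072), which also reversed the hypoxia list (adjusted p = 0.014). Its glucose transporter genes Slc2a3 and Slc2a1 had log2 values of -0.71 and -0.53 (adjusted p = 0.056 and 0.063).

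Among metabolic lists, 2 of 40 respiratory chain genes fell, Ndufa4 and Atp5b, or 0 when adjusted over the list alone (camera adjusted p = 0.027; adjusted p = 0.65 with an estimated correlation), and 2 of 26 cholesterol and fatty acid synthesis genes fell, Elovl6 and Stard4, or 1 when adjusted over the list alone (camera adjusted p = 0.033; adjusted p = 0.65 with an estimated correlation). Both calls ended when the values were rescaled to a common FPKM sum (adjusted p = 0.29 and 0.067), where the respiratory chain median also turned positive, at 0.04, and with the Trdc covariate (adjusted p = 0.26 for each). The respiratory chain call also ended without control mouse 1 or 2 (adjusted p = 0.076 and 0.092) or SLE1.2.3 mouse 1 or 2 (0.059 and 0.065), and the synthesis call under quantile normalization (0.062) and without control mouse 1 (0.080) or SLE1.2.3 mouse 1 or 3 (0.059 and 0.36). With SLE1.2.3 mouse 1 as the lone SLE1.2.3 library the adjusted p was 0.14 for the respiratory chain list and 0.28 for the synthesis list. Ribosomal protein genes had 0 of 30 members past the threshold, also when adjusted over the list alone. The list was lower in the camera test (adjusted p = 0.0094, or 0.71 with an estimated correlation). That call ended under quantile normalization (adjusted p = 0.090) and without SLE1.2.3 mouse 3 (adjusted p = 0.52). It was reversed with the Trdc covariate (adjusted p = 1.7e-12) and with SLE1.2.3 mice 2 and 3 left out (adjusted p = 0.012, from 1 SLE1.2.3 library with the spread of the controls). In the fatty acid oxidation list Acadm, Cpt1a and Etfb rose by 0.49, 0.63 and 0.47, or 4 members when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.053), although it did without control mouse 2 (0.025), SLE1.2.3 mouse 3 (0.032) or SLE1.2.3 mice 2 and 3 (0.042, from 1 SLE1.2.3 library). The antioxidant and iron list had 1 higher and 4 lower of 20, or 2 and 7 when adjusted over the list alone (camera adjusted p = 0.13). Tfrc and Sod2 fell by 0.70 and 0.47, Srxn1 rose by 1.36, and Ftl1, the ferritin light chain gene on chromosome 7, fell from 169 ± 9.32 to 54.0 ± 1.34 FPKM. Ftl1 has a pseudogene copy that rose, so its level is uncertain. Of 21 genes in the amino acid and one-carbon list Slc1a5 fell by 0.69 and Mthfd2 rose by 0.45, with the same counts when adjusted over the list alone (camera adjusted p = 0.59).

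The lists that follow here did not pass the camera test. In the Th2 list Il13 rose by 3.25 on the log2 scale and Il24 fell, 5 of 7 did not pass, and 2 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.60). In the regulatory T cell list Tigit and Entpd1 rose, Izumo1r and Lrrc32 were among 3 of 12 that fell, and 4 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.74). Foxp3, the regulatory T cell factor gene, lay under the filter with 0.275 ± 0.0319 and 1.21 ± 0.458 FPKM in control and SLE1.2.3 cells. In the follicular helper list Pdcd1, Bcl6 and Tox2 rose and Slamf6 fell among 10, or 3 and 3 when adjusted over the list alone (camera adjusted p = 0.76; 0.0014 with the Trdc covariate). For these lists the median, mean and camera direction were negative and the fry direction was positive. In the activation list Nfkbia was among 2 of 19 that rose, and Egr3, Lta and Il2 fell. The counts were the same when adjusted over the list alone (camera adjusted p = 0.11, or 0.047 with the mouse number as a block). Il2 fell from 4.72 ± 1.31 to 1.65 ± 0.758 FPKM. The IL-2 and STAT5 list had 1 of 15 higher and 3 lower, or 4 and 7 when adjusted over the list alone, with Cish lower by a log2 value of -1.09 (camera adjusted p = 0.19; 0.018 when rescaled to a common FPKM sum). In the receptor signalling list 1 of 22 members rose, Ptpn22 by 0.63, and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.76). Its median and fry direction were positive where its mean and camera direction were negative. The median, at 0.015, turned negative when rescaled by median ratio (-0.011) or by quantiles (-0.039). The unfolded protein list had 4 of 20 higher, with Dnajb9 and Herpud1, and Sesn2 and Xbp1 lower, or 5 and 2 when adjusted over the list alone (camera adjusted p = 0.16). Zfp36, Jund and Btg2 were the 3 of 13 immediate early genes that rose, also when adjusted over the list alone (camera adjusted p = 0.45). Of 13 mitochondrial transcripts 0 passed, over all genes or adjusted over the list alone (camera adjusted p = 0.53), with mt-Nd2 at a log2 value of -0.24 and mt-Nd3 at 0.49 (adjusted p = 0.13 and 0.26).

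**Figure D2:**
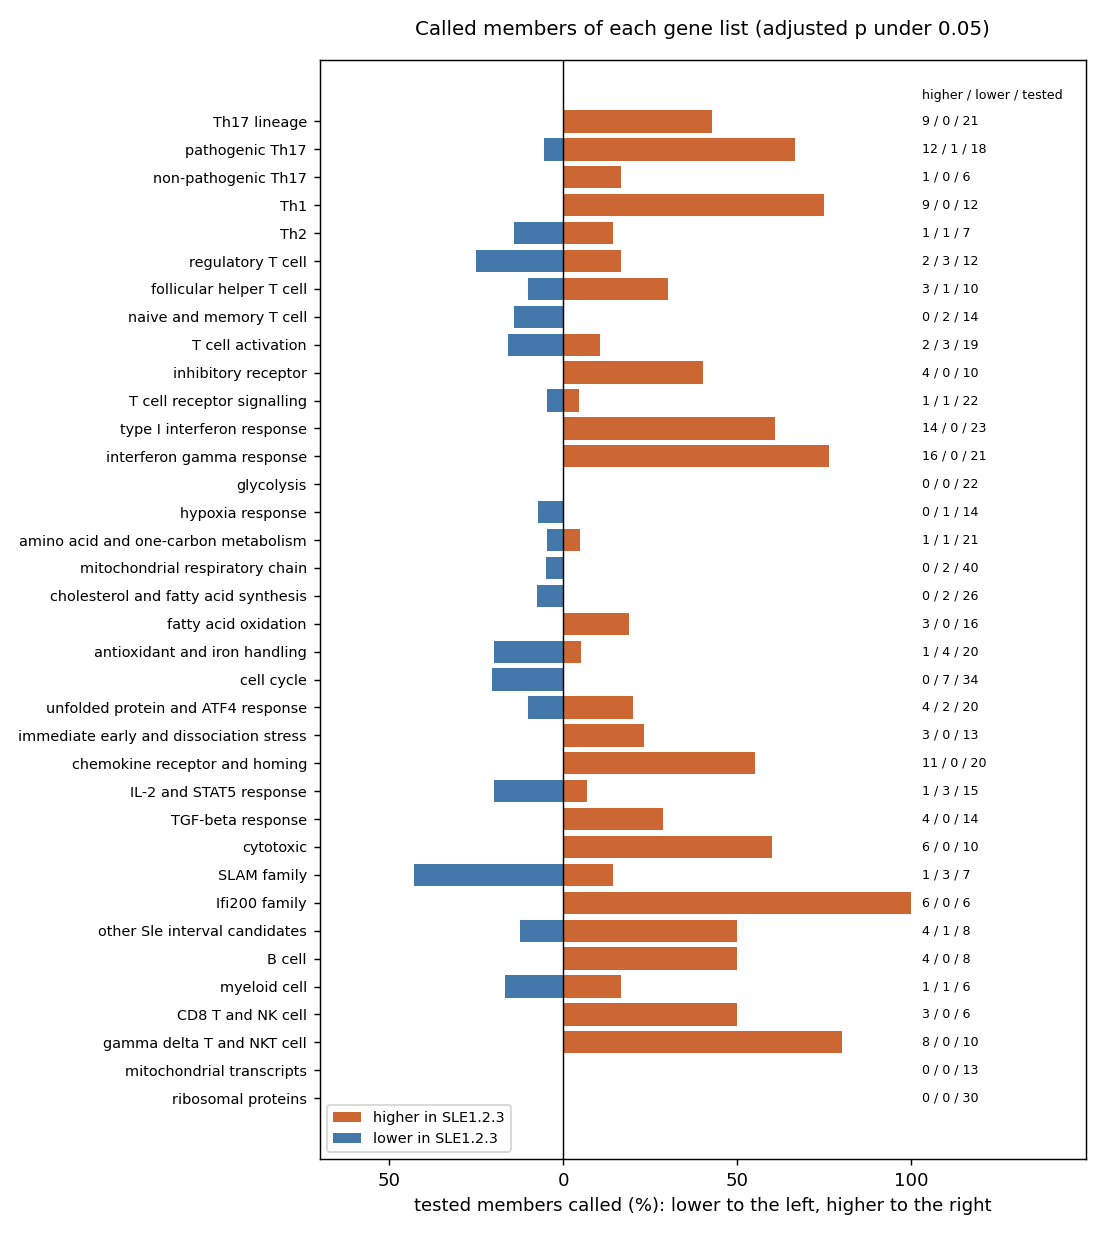
Percentage of the tested members of each gene list that passed, with lower members to the left in blue and higher members to the right in orange, and the numbers higher, lower and tested at the right edge. All 6 tested Ifi200 genes rose, 16 of 21 interferon-γ response genes rose, and 0 of 22 glycolysis genes passed.

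Genes commonly placed in the Sle intervals made up most of 3 lists, which also held the SLAM adaptor gene Sh2d1a. Of 21 tested candidates 15 passed, with 11 higher and 4 lower, and 16 passed when adjusted over these lists alone. The count was 5 without SLE1.2.3 mouse 2, 8 without each of the control mice in turn, and 3 with the Trdc covariate. The SLAM family list holds receptors of lymphocyte contact encoded on chromosome 1 and their adaptors. In it Slamf7, Slamf6 and Slamf1 fell by 1.49, 1.34 and 0.64 on the log2 scale and Cd84 rose by 0.46. When adjusted over the list alone, 1 of 7 was higher and 4 were lower. The list was lower in the camera test (adjusted p = 0.012, or 0.39 with an estimated correlation and 0.55 with the Trdc covariate). Ly9 had 32.0 ± 1.02 and 16.9 ± 7.35 FPKM (adjusted p = 0.071) and did not pass. All 6 tested members of the Ifi200 family, interferon-inducible DNA sensors on chromosome 1, rose, with Aim2, Ifi211, Mndal and Ifi203 at log2 changes of 0.85, 1.26, 1.88 and 1.30 (camera adjusted p = 4.4e-05; adjusted p = 0.39 with an estimated correlation). These genes are close relatives and their reads may be shared. The other candidates had 4 of 8 higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.23). Cdkn2c, a cell cycle inhibitor gene on chromosome 4, fell by 1.25, and Cyfip1, Usf1 and Itgal rose by 0.79, 0.59 and 0.68 on the log2 scale. Fcgr2b lay under the filter, with 0.175 ± 0.0106 and 0.139 ± 0.137 FPKM.

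The last comparison asked whether the genes that passed gathered on the interval chromosomes. On chromosome 7, 189 of 838 tested genes passed, which is 22.6% against 14.6% elsewhere (odds ratio 1.70, 95% limits 1.42 and 2.02; two-sided Fisher's exact test, adjusted p = 1.2e-07 over 21 chromosomes). With a log2 change of at least 1 also required, the odds ratio was 1.45 (adjusted p = 0.11). At any size of change it was 2.55, 2.60 and 2.44 without control mouse 1, 2 and 3, and 1.29, 2.64 and 1.72 without SLE1.2.3 mouse 1, 2 and 3. Chromosome 1 had 18.2% (odds ratio 1.25, adjusted p = 0.17 by Fisher's exact test) and chromosome 4 had 15.8% (odds ratio 1.05, adjusted p = 0.95). Without control mouse 1, 2 or 3 chromosome 1 passed, with odds ratios of 1.78, 2.13 and 1.93, and chromosome 4 passed without control mouse 2 or 3, with 1.82 and 1.81. Of 246 bins of 10 Mb, 5 passed. On chromosome 6, 60000001 to 70000000 had 18 of 32 genes, 18 higher and 0 lower, of which 15 were immunoglobulin segments. On chromosome 13, 10000001 to 20000000 had 15 of 33, 14 higher and 1 lower, of which 9 were T cell receptor segments, among them Trgc1 and Trgc2. Segments near 0 in the controls passed the filter on the mean only through the SLE1.2.3 libraries, so their direction in both bins was largely set by it. On chromosome 7, 40000001 to 50000000 had 30 of 87, 17 higher and 13 lower, and 30000001 to 40000000 had 22 of 65, 10 higher and 12 lower. On chromosome 1, 170000001 to 180000000 had 21 of 59, 14 higher and 7 lower. Genes are not independent replicates, so these tests describe where the called genes lay.

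**Figure D3:**
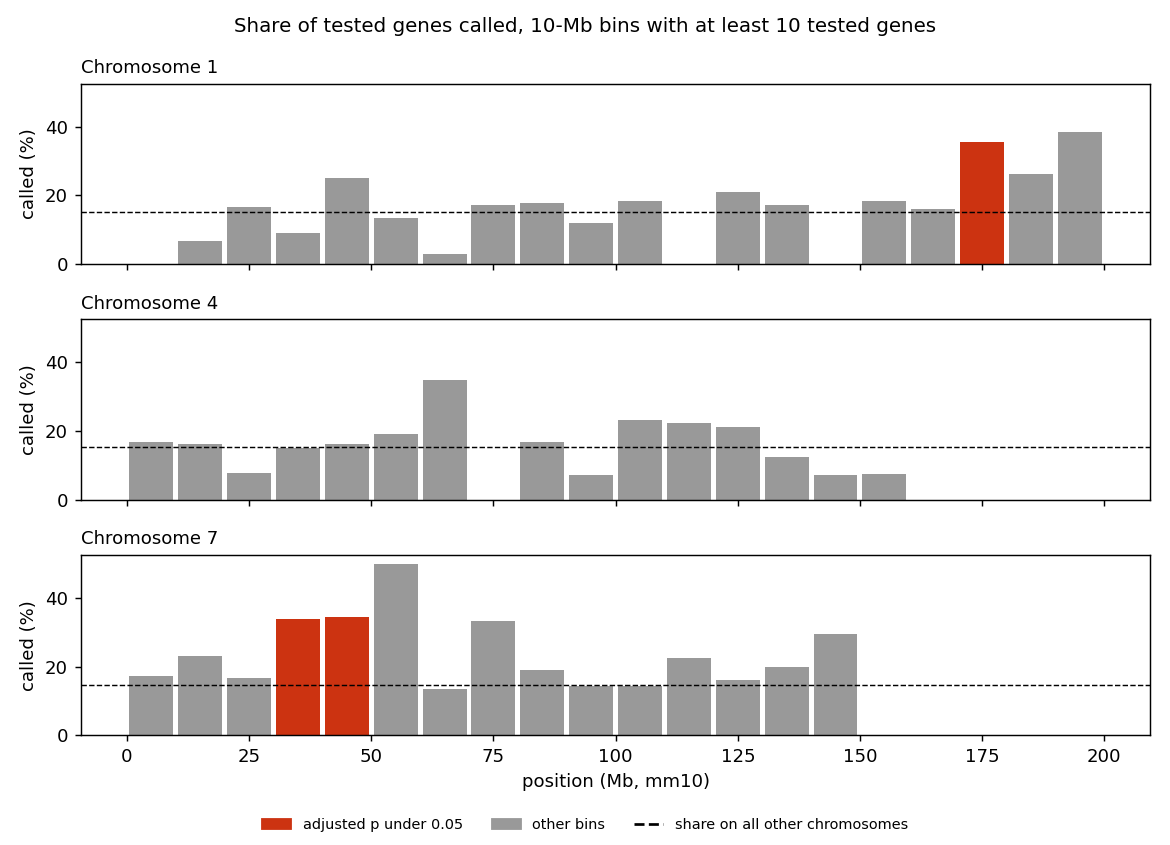
Percentage of tested genes that passed in 10-Mb bins along chromosomes 1, 4 and 7 (position in Mb, mm10), with bins of an adjusted p under 0.05 in red and a dashed line at the percentage on all other chromosomes. The red bins hold 21 of 59 genes on chromosome 1 and 22 of 65 and 30 of 87 genes on chromosome 7.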

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

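The Trdc covariate, the removal of SLE1.2.3 mice 2 and 3, voom and the scaling without ribosomal RNA were chosen after seeing the data, and the other settings before. The 1733 genes past the threshold (1098 higher, 635 lower) became 798 (488, 310) with no filter, 1129 with a mean of at least 5 FPKM (391 lower), 483 (341, 142) with a log2 change of at least 1, 659 (410, 249) without SLE1.2.3 mice 2 and 3, where the lone SLE1.2.3 library is assumed to vary like the controls, and 182 (120, 62) with the Trdc covariate. Array weights gave 6952 (3764, 3188), in a fit that did not converge. Leaving out each mouse gave 206 to 3705 genes, 142 to 2122 higher and 64 to 1583 lower. Rescaling to a common FPKM sum moved the median of all genes to 0.11 and gave 1006 higher and 349 lower (74.2% higher). That sum includes the ribosomal RNA-like Gm23935, at 78767 FPKM in control 3 and 1923 to 3743 FPKM in the other libraries. A common sum thereby lowers the other genes of control 3. With ribosomal, small and mitochondrial RNA left out of the scaling, the median was -5.1e-05, with 1059 higher and 719 lower. Camera's adjusted p was then 0.026, 0.012 and 0.032 for the TGF-β, respiratory chain and synthesis lists. Quantile normalization gave 969 and 893 (52.0% higher), and voom 866 and 704. Under the 4 scalings 0 of the called genes compared changed sign; 2 lay under the filter after rescaling to a common FPKM sum and were not compared. The causes were not tested beyond the smaller number of mice or genes.

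The labels do not say that equal mouse numbers pair the mice. Deviations of mice 1, 2 and 3 correlated at -0.0040, 0.10 and 0.091 across genotypes, and not every mouse correlated best with its own number. With so few mice this does not exclude a pairing. With the number as a block, 940 genes passed (606 higher, 334 lower), and camera's adjusted p was 0.056 for the Th17 list and 0.047 for the activation list. The planned negative binomial count tests were not run, since the file holds no counts.

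Of the list tests, 19 passed, 0 with an estimated correlation and 30 with fry for either direction. Raw p-values of reversed lists, from limma's camera and not exact, were 6.7e-06 (naive and memory), 0.0044 (hypoxia) and 9.2e-14 (ribosomal proteins) with the Trdc covariate, and 0.0046 (ribosomal proteins) without SLE1.2.3 mice 2 and 3. The odds ratio of chromosome 7 was 1.45 with a log2 change of at least 1. Without each mouse in turn it ranged over 1.29 to 2.64, that of chromosome 1 over 1.14 to 2.13 and of chromosome 4 over 1.12 to 1.82. The 15 interval candidates became 9 with a mean of at least 5 FPKM, 9 without SLE1.2.3 mice 2 and 3, 3 with the Trdc covariate, and 5 to 16 without each mouse.

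Over all settings 2285 comparisons of a named gene were unchanged in whether the gene passed, 627 lost the call, 29 gained it and 16 were reversed. A reversal is a change of sign in a gene that passed in the main fit or in that setting. Sign changes in genes that passed in neither are among the 2285. All 16 reversals came with the Trdc covariate, which removes part of any change that moves with it and nearly follows genotype. The values were -0.44 (5830411N06Rik), -0.87 (Blk), 1.22 (Cd4), -1.41 (Cd8b1), 0.29 (Igfbp4), 0.085 (Il24), 0.063 (Izumo1r), -0.10 (Ldlrad4), 0.42 (Lrrc32), 0.18 (Muc13), 0.25 (Selenbp1), 0.42 (Tgm2), -0.073 (Trgc4), -0.23 (Trgv4), -0.58 (Trgv6) and -0.17 (Xcr1). Of the named genes, 80, 84 and 80 lost the call without control mouse 1, 2 and 3, and 89 and 18 without SLE1.2.3 mouse 2 and 3; 95 lost it with the Trdc covariate, 66 with no filter and 36 without SLE1.2.3 mice 2 and 3. Depth limits low genes most in control 3.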

Other observations

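All tests in this part were chosen after the results they bear on had been seen, and their bounds were set with the values at hand. Variable segments of the γδ receptor, chosen after their values were seen, were also higher in SLE1.2.3 cells. Trgv4 was at 3.63, 25.5 and 58.3 FPKM and Trgv6 at 1.58, 6.31 and 18.8 FPKM in SLE1.2.3 libraries 1, 2 and 3, against at most 0.237 and 0.047 FPKM in the controls. Of 171 tested T cell receptor segments 30 passed, 14 of them higher. CT010467.1, a ribosomal RNA-like feature, was at 8822 FPKM in control 3 and between 114.8 and 275.7 FPKM in the other libraries.

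With 3 mice against 3 there are 10 splits of the libraries, too few for a share under 0.05. The real split gave 1733 genes, 1098 higher and 635 lower, and the highest of the other splits gave 0. Thus 1 of the 10 splits, the real one, gave as many. Each other split has libraries of both genotypes on both sides, so the genotype difference enters its spread. Its low count was thus largely set in advance and is no support for the real grouping. For the gene lists the real split gave 19 and the highest of the others 15.

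Like every gene called higher, the called γδ and cytotoxic genes lay above the controls in every SLE1.2.3 library. So did Cd8a and Cd8b1, which did not pass. Library 1 was the lowest of these libraries for each of these γδ, cytotoxic and CD8 genes. FPKM divides depth out, so a difference in depth predicts ratios near 1 and at most 1.61 if uncorrected, and the lowest ratio of means among the 9 γδ markers was 36.7, which argues against it. These markers are the tested members of the γδ and NKT list other than Trac, which CD4 T cells express and which was set apart after the data were seen. A candidate explanation is cells of another type in the SLE1.2.3 cultures: the excess over the controls in library 1, as a share of that in library 3, was at most 0.144 for 8 markers but 0.374 for Zbtb16, against a lower quartile of 0.365 and a median of 0.576 over all genes called higher, and Cd4 and Trac lay below the controls in libraries 2 and 3. This does not decide it: the isolation of naive CD4 T cells should remove such cells, and whether they came through it, expanded in culture, or are CD4 cells that express these genes stays open, as does an effect of the genotype.

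If a single admixed source of fixed composition accounted for the genes called higher, their excess would scale like the markers. For the 6 cytotoxic genes called higher the median excess ratio was 0.0882, inside the marker range of 0.0477 to 0.374. For the 9 Th17 genes called higher it was 0.763 (0.744 to 0.781 against single control libraries), and since the threshold selects against genes that are low in library 1, it was also taken over the 14 Th17 genes with a higher mean, passed or not, where it was 0.732 (0.626 to 0.740). Of all genes called higher 26.6% lay in the range, or 4.64% in that of the 8 markers without Zbtb16, which under that selection decides nothing. Such a source may account for the cytotoxic genes. It is argued against for the Th17 lineage list as a set and for Il17a (0.656 to 0.736), but not for Il22 and Il1r1, which lay in the range. The pathogenic Th17 list was not tested in this way, and its members differed. Ifng and Gzmb lay in the range, at 0.0507 and 0.0935. Csf2 was at 17.7, 31.5 and 23.9 FPKM in SLE1.2.3 libraries 1, 2 and 3, against a control mean of 4.09 FPKM. Several sources, responses to their cytokines, or a change in the CD4 cells stay open.

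Several pseudogenes, named after their values were seen, rose while their source genes fell, and not only on the interval chromosomes: Rpl35a on chromosome 16 fell by 1.69 on the log2 scale while its copies Gm10029, Rpl35a-ps2 and Gm10243 rose. Ftl2-ps was at 0.0203 ± 0.0352 FPKM in control and 213 ± 12.6 FPKM in SLE1.2.3 cells and Ndufs5-ps at 2.26 ± 0.480 and 86.7 ± 5.61 FPKM, while Ftl1 on chromosome 7 and Ndufs5 on chromosome 4 fell by 1.63 and 2.1 on the log2 scale. Reads of strain variant alleles assigned to near-identical copies may be the cause: in a first search of every gene with a protein-coding transcript, 16 of 38 pseudogenes that rose had their closest gene on chromosome 1, 4 or 7 (odds ratio 3.17, limits 1.48 and 6.68; two-sided Fisher's exact p = 0.0014). The search was narrowed to tested protein-coding genes after that output was seen, because Ftl2-ps had matched another pseudogene-like entry, and then gave 18 of 35 against 72 of 383 (odds ratio 4.55, limits 2.1 and 9.9; exact p = 4.2e-05), with 6 distinct source genes lower and 1 higher there, and 1 lower and 3 higher elsewhere. If loss of variant reads in mapping accounted for most genes called on chromosome 7, most of them would be lower. Of these genes 38.6% were lower (exact limits 31.6% and 46.0%), against 36.4% elsewhere. This cannot decide whether such loss accounts for a part of them, since many genes there would be called at the share seen elsewhere. A true effect of the interval alleles stays open as well.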
